A study of Persea americana with 12 samples.

How the data were processed

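The data are RNA-seq libraries of avocado embryogenic callus, 3 each from the lines AN-9 and L3, exposed to filtrate of Rosellinia necatrix or unexposed. Per the submitters' processing notes, the authors used fastp, HISAT2 and DESeq2; no version, counting tool, strand setting or genome build is stated. There is 1 deposited table per line. Read counts per gene are deposited as whole numbers, for the listed genes only. A further set of columns holds signal values that are the deposited counts divided by 1 size factor per library. The FPKM columns were made by the authors, per the file headers. The deposited log2 fold changes, p-values and adjusted p-values compare exposed with unexposed libraries of the line. Each table lists only genes with an adjusted p below 0.05 (highest 0.04998 in both), 12783 genes in AN-9 and 12090 in L3. The p-values and adjusted p-values together give the number of genes adjusted over, 22692 in AN-9 and 22846 in L3. This fits 96.3% of the AN-9 rows and 95.8% of the L3 rows to within 0.5, so 56.3% and 52.9% of the genes are listed. All tests here run on genes already selected for a filtrate response.

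Library totals were inferred from the FPKM columns. In each library 2691 to 2849 of the listed genes imply the same whole-number total, and the other genes with reads imply a higher one. The shared, lowest total was used, from 28639534 to 45593773 reads. At these inferred totals the listed genes hold 71.8 to 80.3% of each library. The filter on low counts removed 312 genes in AN-9 and 270 in L3. The biological coefficient of variation was 0.115 in AN-9, 0.121 in L3 and 0.118 over all 12 libraries. Intervals and floors cover counting error only; the confidence level was 95% and the floor 3 counts over a group.

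Within each line the counts were tested with edgeR 4.0.16 (R 4.3.3; TMM, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood test, two-sided, Benjamini-Hochberg, adjusted p below 0.05, no fold threshold) on the 6 libraries of the line. Standard errors are the log2 change divided by the root of the F statistic. The difference between responses and the differences between lines were tested in 1 fit of 12 libraries and 4 group means, on the 10415 shared genes that pass the filter. CPM are counts scaled by the TMM library sizes of the line to a common library size. Groups come from the sample labels, and columns were matched to samples by the names in the labels.

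The 32 gene lists were fixed as words to be found in the gene descriptions. Once the files were seen they were matched to the recommended protein name alone, since whole descriptions mix several sources; the whole description is an alternative. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, on log2 CPM with a prior count of 2, for lists with at least 5 tested members, against the other genes of the table. Putting list members without reads in a group (6 in AN-9, 3 in L3) at their floor moved no list median in either line. Named genes are the 5 largest rises and 5 largest falls per line, among called genes with a mean of at least 50 normalized counts in a group and no overlap between the groups' libraries. To these come the called member of each list with the largest change under the same conditions, the 5 largest differences each way between the responses, and the same between exposed lines.

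The sample labels number the replicates 1 to 3 in each group. In AN-9 the deviations from the group means of samples with the same number correlated at 0.167, 0.187 and 0.158 across genes, all above 0.1. These numbers were therefore taken to pair the AN-9 samples. The labels do not state a pairing, and correlations of this size among 3 replicates do not establish it. The main tests have no block, as fixed before the data were examined.

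The tests were tried on simulated counts with the means, totals and spread of these libraries and 200 changed genes. In the data far more genes were called, 12464 of 12471 in AN-9 and 11800 of 11820 in L3. Between the lines 2859 of 10415 were called exposed and 3346 unexposed. Recovered and false shares depend on how many genes change, so those simulated for these 4 comparisons may not hold in the data. For the filtrate response in AN-9 (12704 genes simulated), 46.3% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 18 of 175 calls false (10.3%). In L3 (12036 genes) these shares were 44.8%, 80.6% and 97.0%, with 7 of 155 calls false (4.52%). For the difference of responses (10371 genes) they were 31.3%, 77.6% and 93.9%, with 7 of 142 false (4.93%), for L3 against AN-9 exposed (10371 genes) 59.7%, 95.5% and 98.5%, with 13 of 182 false (7.14%), and for the unexposed lines (10371 genes) 56.7%, 89.6% and 98.5%, with 11 of 174 false (6.32%). DESeq2 1.42.0 called 40 of 203 falsely in AN-9 (19.7%) and 26 of 191 in L3 (13.6%). Of 32 simulated sets of 50 genes, camera called the 1 that was shifted by 0.5 on the log2 scale and no other. The genes were simulated independently, so this cannot tell how often camera calls lists whose members vary together. In the data the estimated correlation was 0.316 for ribosomal proteins in AN-9 and 0.543 for the vascular list in L3. It was -0.0032 for heat shock in AN-9 and -0.013 for NAC factors in L3, both below the preset 0.01. These 2 lists also lost their calls with an estimated correlation, so members that vary together do not account for that. With an estimated correlation camera tests on the few residual degrees of freedom of the fit. A list not called there is therefore not shown to be unchanged.

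Alternatives set before the data were examined were DESeq2 size factors, no low-count filter, a mean of at least 50 normalized counts, the DESeq2 Wald test, a log2 change of at least 1, the replicate number as a block, all 12 libraries in 1 fit, each library left out in turn, prior counts of 0.5 and 5 for the lists, and a correlation estimated per list. Added afterwards were the deposited size factors, the sum of listed reads as library size, adjustment over the authors' number of genes, matching on the whole description, and, between the lines, the higher minimum mean and every alternative for the lists. Pseudocount alternatives for gene tests do not apply, since counts were tested. Every sample was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.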

Results

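RNA was sequenced from embryogenic callus of avocado, an undifferentiated tissue able to form embryos, grown in darkness from the cultivar Anaheim. L3 is a callus line selected on culture filtrate of Rosellinia necatrix, the fungus that causes white root rot, and it survives medium with 80% filtrate. AN-9 is a control line without that selection. Each line was sampled after 24 h in medium with 40% filtrate (exposed) or without filtrate (unexposed), with 3 libraries in each of the 4 groups and 12 in all. The library totals ranged from 28639534 to 31556923 reads in exposed AN-9, from 32627467 to 35085027 in unexposed AN-9, from 34291468 to 45593773 in exposed L3 and from 30034538 to 37202699 in unexposed L3. Each deposited table lists only genes that the authors called changed in that line, 12783 genes in AN-9 and 12090 in L3, so a gene that is not listed has no value here. Gene names are those of the best protein match in the files and were not checked in avocado. Coordinates are on contigs of a genome build that the sources do not name. Members of large gene families can share reads, so the level of a single member is less certain than the direction of its family. Each line is 1 line, and the labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

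The response of AN-9 to filtrate answers how callus without selection reacts to fungal exudates. In AN-9, 24 h in filtrate raised 50 of 68 heat shock genes and lowered 198 of 204 ribosomal protein genes and 91 of 109 cell cycle genes. The proteinase inhibitor Pag64949 reached 8226 ± 653 CPM (counts scaled to a common library size) in exposed AN-9 against 375 ± 20.7 in unexposed AN-9 (SD, n = 3), a log2 change of 4.46 (edgeR, adjusted p = 7.69e-09). Pag246776, named HOTHEAD after a protein of cuticular lipid synthesis, rose from 10.5 ± 0.866 to 1488 ± 179 CPM (SD, n = 3), a log2 change of 7.15 (edgeR, adjusted p = 3.67e-09). Cyclin-A1-3 (Pag97309), a regulator of cell division, fell from 104 ± 16.9 to 0.741 ± 0.152 CPM (SD, n = 3), a log2 change of -7.12 (edgeR, adjusted p = 8.30e-09).

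Among the largest rises in AN-9 were genes hardly read without filtrate. The thaumatin-like gene Pag344126, of a family of antifungal pathogenesis-related proteins, had no read in the unexposed libraries and 276 in the exposed ones, which makes it at least 116-fold higher against a floor of 3 counts over the group. Nicotianamine synthase (Pag242850), which makes a metal chelator, had 1 read unexposed and 220 exposed, a ratio of 278 (95% exact binomial interval 49.4 to 11000). The lignin-forming anionic peroxidase Pag92571 had 1 read unexposed and 202 exposed, a ratio of 255 (95% exact binomial interval 45.3 to 10100). Without unexposed library 1, which held the single read of both, these 2 genes were at least 60.9-fold and 56.0-fold higher, and Pag344126 at least 76.5-fold. Without unexposed library 2 the ratios were 184 (32.7 to 7300) and 169 (30 to 6710), and Pag344126 was at least 77.0-fold higher. The chloroplastic small heat shock protein Pag81308 rose by 7.36 on the log2 scale, to 357 ± 89.2 CPM (SD, n = 3). Among the largest falls, WALLS ARE THIN 1 (Pag371182), a vacuolar auxin transporter of cells with secondary walls, had 197 reads unexposed and none exposed, so it was at least 51.9-fold lower against the same floor. The leucine-rich repeat gene Pag77178 was likewise at least 47.2-fold lower, from 179 reads to none. Without exposed library 2 or 3 these limits were 33.9 and 34.5 for Pag371182 and 30.8 and 31.3 for Pag77178. Feruloyl-CoA ortho-hydroxylase 1 (Pag133582), which makes the precursor of the coumarin scopoletin, changed by -7.90 on the log2 scale, the F-box gene Pag147735 by -7.69 and Pag146777, which has no name in the files, by -7.51. Without exposed library 2 Pag146777 had 2 reads exposed and 1226 unexposed, a ratio of 317 (95% exact binomial interval 87.5 to 2620).

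The words of the 32 lists were fixed before the data were examined, and matching them to the protein name was chosen after the files were seen. In AN-9, 7 lists were called by camera, which compares a list with the other listed genes. Ribosomal protein genes fell in 198 of 204 cases with a median log2 change of -1.05 (adjusted p = 8.21e-17), as in 60S ribosomal protein L18-2 (Pag275919), which fell by 2.17 on the log2 scale. Cell cycle and DNA replication genes had a median of -1.74 (adjusted p = 4.66e-08). All 8 vascular and xylem genes fell, with a median of -1.71 (adjusted p = 0.00996, and 0.568 with membership read from the whole description), among them SIEVE ELEMENT OCCLUSION A (Pag286889), a phloem filament protein, at -5.00. Heat shock genes had a median of 1.20 (50 rose, 18 fell, adjusted p = 0.00142). Genes of sugar transport and starch breakdown rose in 42 of 58 cases (adjusted p = 0.0129), with beta-amylase 3 (Pag74459), an enzyme that degrades starch, at 4.92 (5.60 without unexposed library 2). ABC and MATE transporter genes rose in 62 of 90 cases (adjusted p = 0.0183), although the member with the largest change, ABC transporter G family member 5 (Pag389604), fell by 4.46. Photosynthesis genes rose in 19 of 23 cases in this dark-grown callus (adjusted p = 0.0183), with a rubisco activase (Pag274275, not listed in L3) at 2.96. With an estimated correlation no list was called, with adjusted p = 0.526 for ribosomal proteins, adjusted p = 0.393 for the cell cycle, vascular and photosynthesis lists, adjusted p = 0.251 for heat shock, adjusted p = 0.58 for sugars and adjusted p = 0.554 for transporters. For heat shock the estimated correlation was -0.0032, below the preset 0.01, so members that vary together do not account for the lost call. Counts of members that rose or fell, adjusted over the list alone, were the same as those over all genes tested. With 12464 of 12471 genes called, this was nearly fixed in advance. Such counts, in both lines, are shares of genes that the authors listed as changed, not of whole families.

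Lists linked to defence went both ways in AN-9 and were not called. Salicylate genes rose in 13 of 17 cases (adjusted p = 0.0822, and 0.0434 with the replicate number as a block), with salicylic acid-binding protein 2 (Pag325474), which releases salicylate from its methyl ester, at 4.35. The salicylate list had adjusted p = 0.702 with the whole description and 0.393 with an estimated correlation. Genes for protease and polygalacturonase inhibitors rose in 9 of 10 cases (adjusted p = 0.0695). That list had adjusted p = 0.0434 with the block, 0.044 without exposed library 2 and 0.0433 with no filter on low counts. It had adjusted p = 0.361 with the whole description and 0.58 with an estimated correlation. Its member with the largest change, Kunitz trypsin inhibitor 2 (Pag259067), fell from 271 reads to 1, a ratio of 214 (95% exact binomial interval 38.1 to 8490). Without exposed library 3, which held that read, the gene was at least 47.4-fold lower, and without exposed library 2 the ratio was 140 (24.9 to 5550). Terpenoid synthesis rose in 11 of 14 cases (adjusted p = 0.0779), NAC factors in 27 of 39 (0.0717), calcium signalling in 67 of 112 (0.124), receptors in 121 of 204 (0.254) and hypoxia and fermentation in 9 of 12 (0.256). Jasmonate genes rose in 14 of 23 cases (0.382), with allene oxide synthase (Pag171015), the enzyme that commits lipid precursors to jasmonate, at 2.91. WRKY factors rose in 27 of 46 cases (0.354), glutathione S-transferases in 11 of 18 (0.353), mineral nutrient genes in 43 of 76 (0.385), abscisic acid genes in 15 of 26 (0.403), scavengers of reactive oxygen in 14 of 26 (0.491) and pathogenesis-related genes in 32 of 60 (0.634). Peroxidases (17 of 33) and UDP-glycosyltransferases (17 of 33) both had adjusted p = 0.702, cytochromes P450 rose in 34 of 67 cases (0.837), proteases in 47 of 91 (0.878) and MYB factors in 38 of 76 (0.95). Falls prevailed in cell wall remodelling (89 of 141, adjusted p = 0.0882), where endoglucanase 17 (Pag167988) fell by 6.24 on the log2 scale, and in auxin (35 of 54, 0.246), flavonoid (17 of 25, 0.256), phenylpropanoid (31 of 51, 0.404), embryo maturation (11 of 18, 0.529) and ethylene genes (41 of 76, 0.741). The median, mean and test differed in sign for cytochromes P450, proteases and MYB factors.

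Other named genes of AN-9 that rose were, on the log2 scale, UDP-glycosyltransferase 86A1 (Pag186928) at 6.35, cytochrome P450 714C2 (Pag82742) at 5.86, the ethylene-responsive factor ERF019 (Pag26291) at 5.49, ABSCISIC ACID-INSENSITIVE 5-like protein 2 (Pag56827) at 4.11, glutathione S-transferase parC (Pag84135) at 3.96, a geranylgeranyl pyrophosphate synthase subunit (Pag361206) at 3.58 and WRKY transcription factor 75 (Pag364167) at 3.32 (3.98 without unexposed library 2). Basic 7S globulin (Pag55135) rose by 3.29, L-lactate dehydrogenase A (Pag36715) by 2.53 and catalase isozyme 1 (Pag152690) by 2.50. CUP-SHAPED COTYLEDON 2 (Pag33979), a regulator of organ boundaries, changed by -5.50, the protease SBT1.6 (Pag165971) by -5.45, the auxin-responsive gene SAUR50 (Pag198029) by -5.20, a leucine-rich repeat receptor kinase (Pag125650) by -4.80, calcium-binding protein CML25 (Pag282614) by -4.55, shikimate O-hydroxycinnamoyltransferase (Pag35656), of lignin synthesis, by -4.50, the Myb-related Pag310355 by -4.26 and leucoanthocyanidin dioxygenase (Pag239272), of flavonoid synthesis, by -2.79. All exposed reads of Pag33979 and Pag198029, 5 each, were in exposed library 2. Without it both genes had none exposed and were at least 52.5-fold and 42.9-fold lower.

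In the edgeR quasi-likelihood test 12464 of the 12471 AN-9 genes tested were called, 6180 higher and 6284 lower, and 5406 of these changed at least 2-fold. These genes had been selected by the authors from 22692 on the same libraries, so the count is not independent evidence; adjusted over 22692 genes, 12240 were called.

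**Figure D1:**
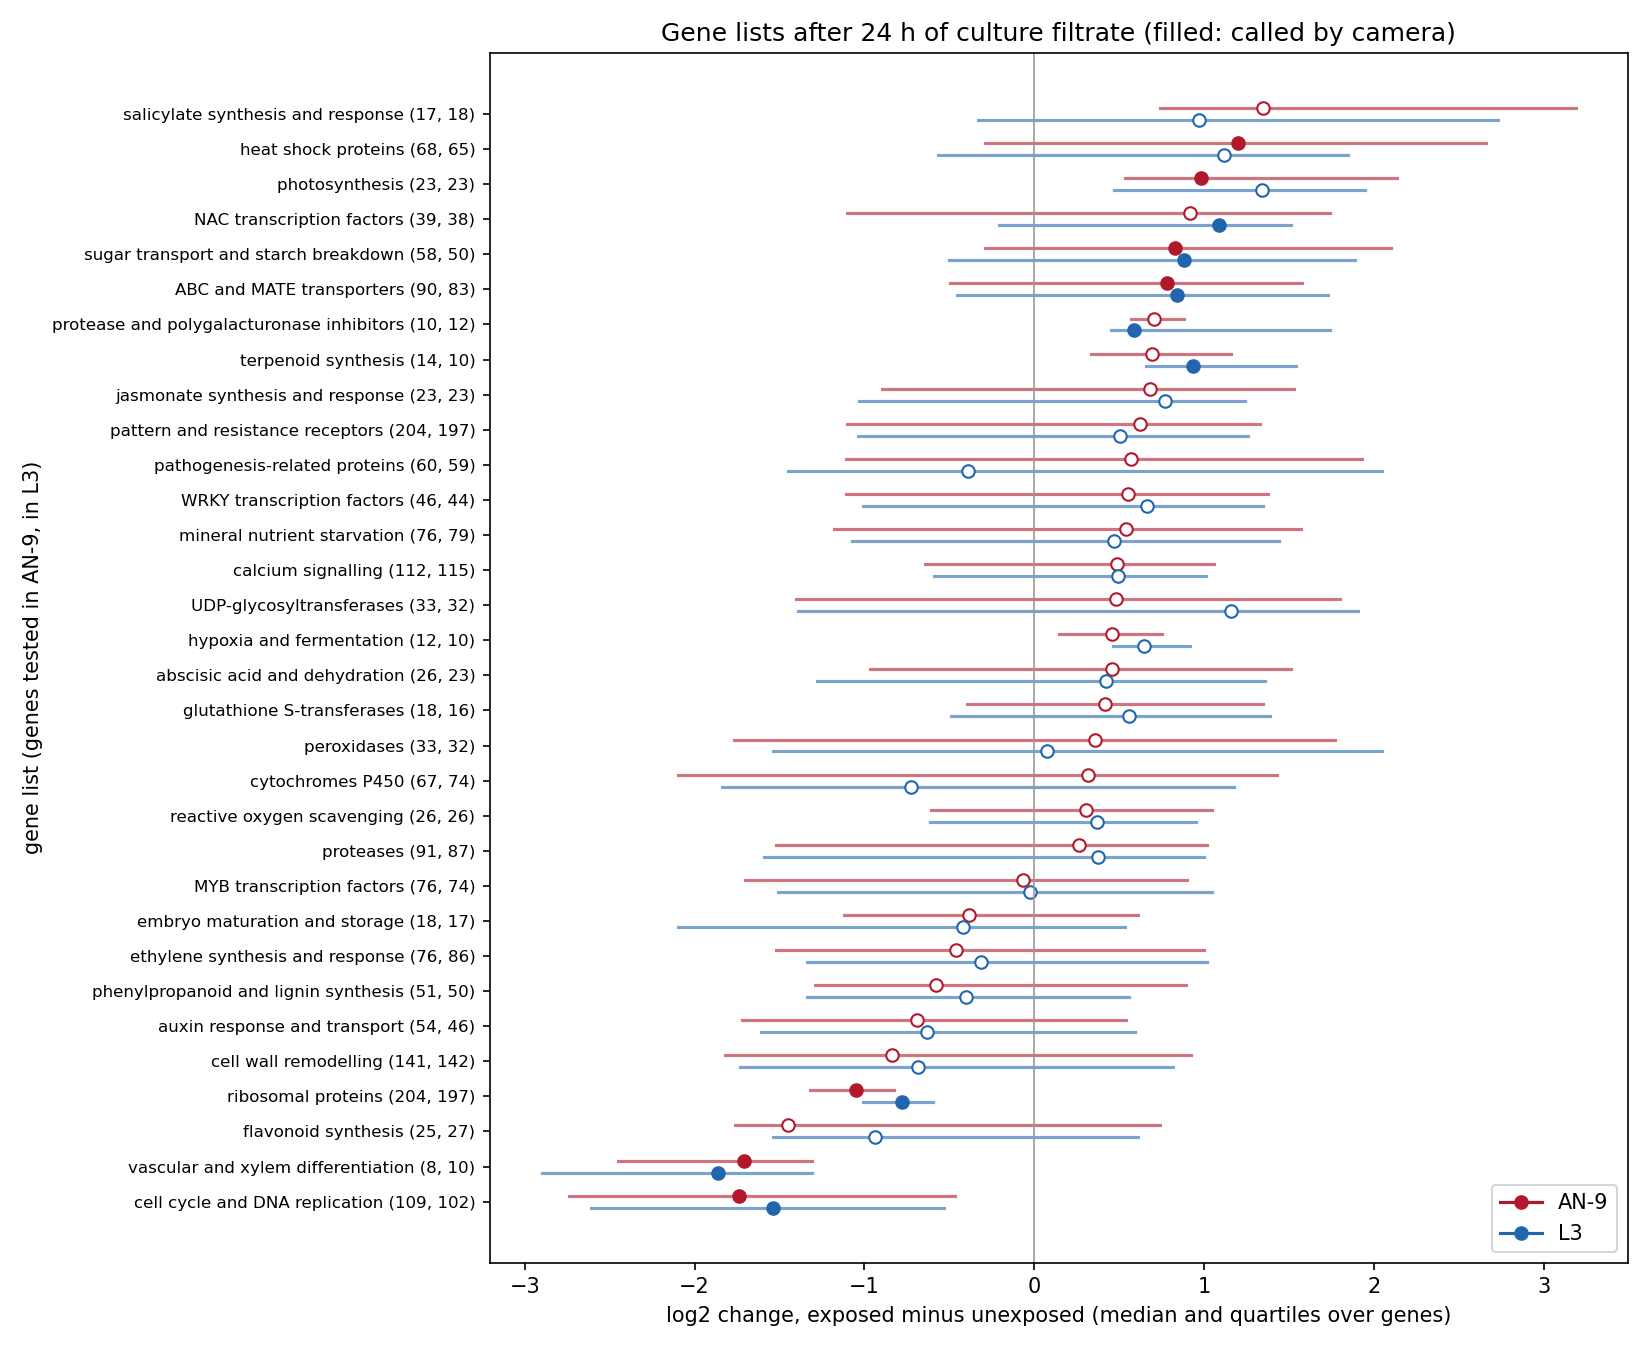
Median log2 change (points) and quartiles (lines) over the genes of each of 32 lists, exposed minus unexposed, in AN-9 (red) and L3 (blue); filled points were called by camera. The cell cycle, vascular and ribosomal lists lie below 0 in both lines, with ribosomal medians of -1.05 in AN-9 and -0.78 in L3.

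The response of L3 answers how the selected line reacts to the same filtrate. In L3, filtrate lowered 192 of 197 ribosomal protein genes and 86 of 102 cell cycle genes, and raised 59 of 83 ABC and MATE transporter genes and 11 of 12 genes for protease and polygalacturonase inhibitors. The proteinase inhibitor Pag64949 rose from 138 ± 11.3 to 6693 ± 186 CPM (SD, n = 3), a log2 change of 5.60 (edgeR, adjusted p = 1.71e-08). HOTHEAD (Pag246776) rose from 4.59 ± 0.940 to 860 ± 103 CPM (SD, n = 3), a log2 change of 7.55 (edgeR, adjusted p = 1.99e-08). The thaumatin-like gene Pag308947 rose by 6.82 on the log2 scale to 88.7 ± 8.13 CPM, and omega-hydroxypalmitate O-feruloyl transferase (Pag369420), which adds ferulate to suberin monomers, by 6.47 to 125 ± 15.2 (SD, n = 3).

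Further large rises in L3 came from near 0. The lignin-forming peroxidase Pag92571 had 1 read unexposed and 205 exposed, a ratio of 195 (95% exact binomial interval 34.5 to 7720). Without unexposed library 1, which held that read, it was at least 41.7-fold higher, and without library 2 the ratio was 126 (22.3 to 4980). Pag321196, matched to an enzyme of purine synthesis, had 2 reads unexposed and 279 exposed, a ratio of 132 (95% exact binomial interval 36.3 to 1100; 85.2, from 23.4 to 707, without unexposed library 1). Among the largest falls, DOWNY MILDEW RESISTANCE 6 (Pag140165), an oxygenase that removes salicylate, went from 275 reads to 1, a ratio of 290 (95% exact binomial interval 51.6 to 11500); in AN-9 it had 44 reads unexposed and none exposed, at least 11.6-fold lower (7.58-fold without AN-9 exposed library 2 and 7.70-fold without 3). Without L3 exposed library 3, which held the single read, it was at least 70.1-fold lower in L3, and without exposed library 1 or 2 the ratio was 178 (31.7 to 7060) or 191 (34.0 to 7570). The uncharacterized gene Pag94672 fell from 549 reads to 2, a ratio of 289 (95% exact binomial interval 79.7 to 2390; 191, from 52.5 to 1580, without exposed library 2), and Pag85659, with an initiation factor 4B domain, from 490 to 2, a ratio of 258 (95% exact binomial interval 71.1 to 2140). Without exposed library 3, which held both reads, Pag85659 was at least 125-fold lower, and without exposed library 1 or 2 the ratio was 159 (43.7 to 1310) or 170 (46.8 to 1410). The F-box gene Pag147735 changed by -8.04 on the log2 scale and the unnamed Pag263622 by -8.00. Without exposed library 1 Pag263622 had 1 read exposed and 1545 unexposed, a ratio of 1000 (95% exact binomial interval 179 to 39500).

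In L3, 8 of the 32 lists were called by camera. Ribosomal protein genes had a median of -0.78 (adjusted p = 8.43e-16), as in 60S ribosomal protein L36-3 (Pag292465) at -1.71. Cell cycle genes had a median of -1.54 (adjusted p = 3.29e-08), as in cyclin-dependent kinases regulatory subunit 1 (Pag192964) at -7.26. Without exposed library 1 that gene had 3 reads exposed and 2078 unexposed, a ratio of 449 (95% exact binomial interval 153 to 2180). All 10 vascular genes fell (median -1.86, adjusted p = 0.00937), with SIEVE ELEMENT OCCLUSION A (Pag286889) at -5.27 (-6.05 without exposed library 1). The transporter list had adjusted p = 0.00632, with ABC transporter G family member 9 (Pag351543) at 3.74 (4.41 without unexposed library 1), and the inhibitor list adjusted p = 0.0218. NAC factors rose in 28 of 38 cases (adjusted p = 0.029), although CUP-SHAPED COTYLEDON 2 (Pag253076) fell by 4.29. Terpenoid synthesis rose in 9 of 10 cases (adjusted p = 0.0435), with the geranylgeranyl pyrophosphate synthase subunit Pag361206 at 3.06 (3.74 without unexposed library 2). Sugar transport and starch breakdown rose in 34 of 50 cases (adjusted p = 0.0435), although sugar transport protein 5 (Pag153109) fell by 4.55. The sugar list lost its call with the replicate number as a block. With an estimated correlation each of the 8 lists had adjusted p = 0.563 and none was called. With membership read from the whole description instead of the protein name, 3 of the 8 were called, the transporter, cell cycle and ribosomal lists.

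Heat shock genes rose in 44 of 65 cases in L3 and were not called as a list (adjusted p = 0.0712). They were called without exposed library 1 (0.0374) or 2 (0.0477) and with the replicate number as a block. The heat shock list had adjusted p = 0.2 with the whole description and 0.682 with an estimated correlation. Heat shock factor HSF30 (Pag365527), a regulator of chaperone genes, rose by 4.67. Photosynthesis genes rose in 18 of 23 cases (adjusted p = 0.0547; 0.0474 without exposed library 2, 0.0472 without exposed library 3, 0.0495 with no filter on low counts and 0.0312 with the whole description), with the rubisco activase Pag247630 at 2.73. Hypoxia genes rose in 9 of 10 cases (adjusted p = 0.0533; 0.0439 without unexposed library 3, 0.0378 without exposed library 1 and 0.0477 without exposed library 2), with L-lactate dehydrogenase A (Pag36715) at 2.25. The photosynthesis and hypoxia lists were also called with the block, and each had adjusted p = 0.563 with an estimated correlation. With the whole description the hypoxia list had adjusted p = 0.285. Of the other lists, rises prevailed in calcium signalling (70 of 115, adjusted p = 0.109), salicylate (13 of 18, 0.14), WRKY (27 of 44, 0.263), receptor (112 of 197, 0.328), jasmonate (15 of 23, 0.328), glutathione S-transferase (10 of 16, 0.328), UDP-glycosyltransferase (18 of 32, 0.328), abscisic acid (13 of 23, 0.571), reactive oxygen (14 of 26, 0.577), mineral nutrient (41 of 79, 0.577) and protease genes (47 of 87, 0.727). Falls prevailed in cell wall remodelling (89 of 142, adjusted p = 0.0859), flavonoid (19 of 27, 0.17), phenylpropanoid (31 of 50, 0.328), auxin (28 of 46, 0.337), embryo maturation (11 of 17, 0.42), cytochrome P450 (42 of 74, 0.577) and ethylene genes (45 of 86, 0.937). Peroxidases had 15 rises and 16 falls among 32 (0.727), MYB factors split 37 to 37 (0.957) and pathogenesis-related genes 29 to 29 (0.881). The median, mean and test differed in sign for pathogenesis-related genes and proteases.

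Other named genes of L3 also rose. DMR6-LIKE OXYGENASE 2 (Pag364610) rose by 4.63 on the log2 scale (4.03 without unexposed library 2), the calmodulin-binding kinase Pag308756 by 4.60, abscisic acid 8'-hydroxylase 2 (Pag174105), which degrades abscisic acid, by 4.50, sulfate transporter 3.1 (Pag219550) by 3.88, WRKY76 (Pag306446) by 3.63, allene oxide synthase (Pag171020) by 3.49 and a flavonoid 3-O-glucosyltransferase (Pag320431) by 2.81. Expansin-A6 (Pag307412), which loosens cell walls, changed by -6.56, the receptor-like kinase IMK3 (Pag280626) by -5.58, the auxin efflux carrier Pag153714 by -4.70 and 1-Cys peroxiredoxin PER1 (Pag111985) by -3.02. The aspartic protease Pag93496 fell from 167 reads to 2, a ratio of 88.0 (95% exact binomial interval 24.0 to 732). Without exposed library 2, which held both reads, it was at least 38.6-fold lower, and without exposed library 1 the ratio was 54.1 (14.7 to 450). Allene oxide synthase Pag171015 and Pag171020 lie next to each other on contig Ctg0263 (125196 to 125996 and 126080 to 126789) and may share reads.

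In the edgeR test 11800 of the 11820 L3 genes tested were called, 5877 higher and 5923 lower, 4649 of them at least 2-fold. Adjusted over the 22846 genes from which the authors had selected these, 11567 were called.

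Whether both lines respond with the same genes was asked of the 10452 genes listed in both. HOTHEAD, the proteinase inhibitor Pag64949, both thaumatin-like genes, cytochrome P450 714C2 (Pag82742, 5.86 in AN-9 and 5.79 in L3) and parC (Pag84135, 3.96 and 4.22) rose in each line, and cyclin-A1-3 (-7.12 and -6.85) and the F-box gene Pag147735 fell in each. Of the 10452 genes, 10435 had the same direction in the authors' tables and 17 the opposite one. The authors' lists shared 5223 rises and 5212 falls, where independent lists of those sizes among 22692 genes would share 1719 and 1686. Among the genes called in the tests here, 5092 rises and 5152 falls were shared. Across 10272 genes, which are not independent replicates, log2 changes in the lines had r = 0.965 and rho = 0.975. All these genes had been called changed in both lines by the authors. Genes with small changes or called in 1 line alone are left out, so the shared direction and these correlations do not describe all genes. The median absolute log2 change was 0.965 in AN-9 and 0.837 in L3, and 30.8% of the genes had the larger change in L3. The tables listed 2331 genes in AN-9 alone and 1638 in L3 alone, and a difference between the lines could not be tested for these.

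**Figure D2:**
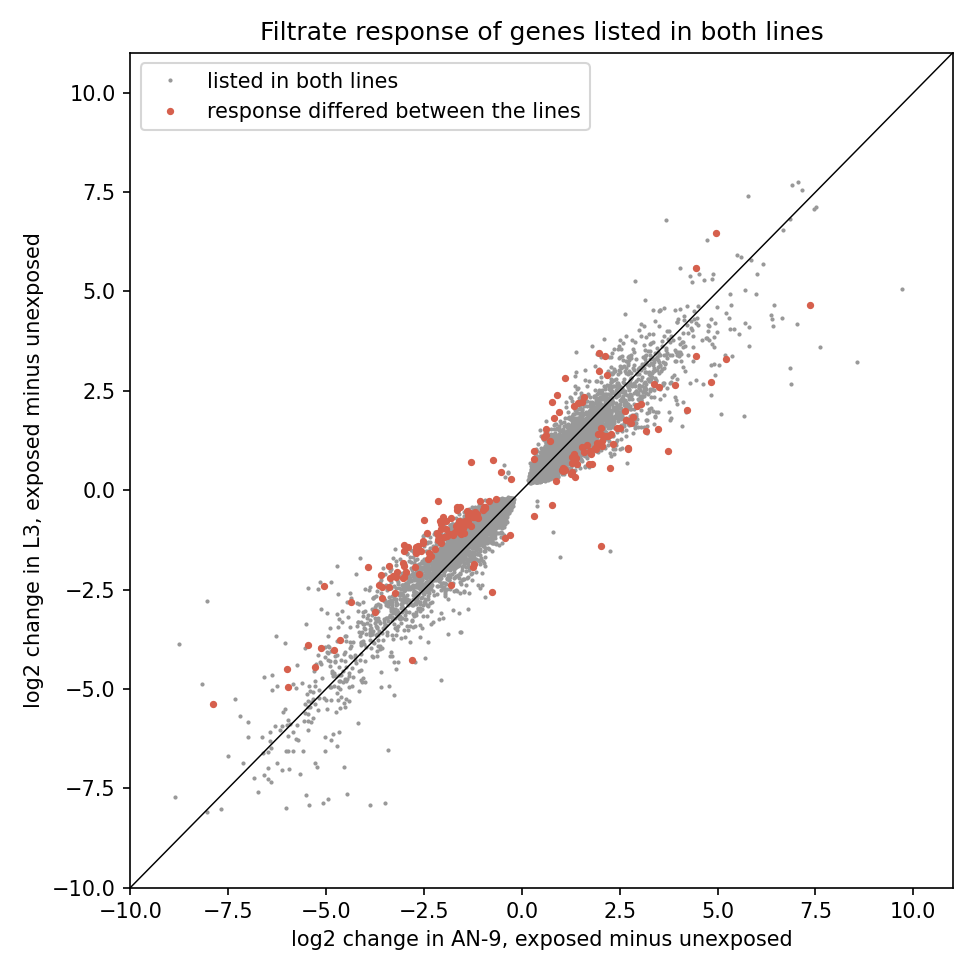
Log2 change in L3 (vertical axis) against log2 change in AN-9 (horizontal axis), exposed minus unexposed, for genes listed in both tables; the line marks equal changes. Red points are genes whose response differed between the lines in the edgeR test, 158 of 194 with the smaller change in L3.

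The difference between the responses of L3 and AN-9 asks which of the genes listed in both lines react otherwise in L3. Genes listed in 1 line alone could not be tested, and 1 tolerant line cannot speak for tolerance in general. Ribosomal protein genes fell less in L3, by a median of 0.26 on the log2 scale over 196 genes (camera, adjusted p = 3.67e-18), and heat shock genes rose less, by a median of -0.27 over 60 genes (camera, adjusted p = 3.44e-05), though with an estimated correlation both had adjusted p = 0.951. The cationic peroxidase 2 gene (Pag57402) fell from 246 ± 60.9 to 55.3 ± 11.4 CPM in AN-9 and stood at 151 ± 14.0 unexposed and 125 ± 14.0 exposed in L3 (SD, n = 3), a difference of 1.86 ± 0.24 on the log2 scale (SE; edgeR, adjusted p = 0.00616). The proteinase inhibitor Pag64949 rose more in L3, by 1.12 ± 0.13 (SE; edgeR, adjusted p = 0.00598), as did omega-hydroxypalmitate O-feruloyl transferase (Pag369420), by 1.49 ± 0.21 (SE; edgeR, adjusted p = 0.00651). Both had lower unexposed levels in L3 and were still lower there in filtrate, with log2 differences from AN-9 of -0.33 and -0.43. In filtrate both lost their call without AN-9 exposed library 2 or L3 exposed library 2. Pag64949 also lost it without L3 exposed library 3 (edgeR, adjusted p = 0.0513), and Pag369420 without AN-9 exposed library 1 (edgeR, adjusted p = 0.056). Cell morphogenesis protein PAG1 (Pag195767) rose to 158 ± 28.1 CPM in AN-9 and to 26.3 ± 4.39 in L3 (SD, n = 3), a difference of -1.93 ± 0.25 (SE; edgeR, adjusted p = 0.00616).

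The ribosomal list's smaller fall came with a lower unexposed level, since unexposed L3 lay below unexposed AN-9 by a median of -0.36 and exposed L3 below exposed AN-9 by -0.10. In the heat shock list unexposed L3 lay above unexposed AN-9 by a median of 0.28 (adjusted p = 0.0239, and adjusted p = 0.795 with an estimated correlation), and exposed L3 against exposed AN-9 had a median of -0.15 (adjusted p = 0.492). The unexposed call was also lost with the whole description (0.0758) and without AN-9 unexposed library 1 (0.0633) or L3 unexposed library 2 (0.131). In that list the chloroplastic small heat shock protein Pag81308 differed by -2.71, from 2.17 ± 0.364 to 357 ± 89.2 CPM in AN-9 and from 5.96 ± 2.75 to 152 ± 79.9 in L3 (SD, n = 3). Adjusted over the list alone, 43 ribosomal genes responded more positively and 10 heat shock genes less in L3, against 6 and 2 over all genes tested. The other 30 lists had adjusted p from 0.116 to 0.944. Of these, the cell cycle list was called without AN-9 unexposed library 1 (adjusted p = 0.0168), AN-9 exposed library 3 (0.0147) or L3 exposed library 3 (0.00135), the flavonoid list without AN-9 unexposed library 3 (0.00209) or L3 exposed library 2 (0.0379), and the sugar list without AN-9 unexposed library 1 (0.0233). With the whole description the cell cycle (0.0436) and jasmonate lists (0.0427) were called too.

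Single genes with the largest differences included a Rac-like GTPase, ARAC11 (Pag366124), a switch of polar growth. ARAC11 fell by 1.30 on the log2 scale in AN-9 and rose by 0.70 in L3, a difference of 1.98 (edgeR, adjusted p = 0.0114), though L3 exposed library 2, at 11.3 CPM, lay within the unexposed range, and the rise in L3 was not called without L3 unexposed library 1 (0.0603) or 2 (0.0588) or L3 exposed library 1 (0.102) or 3 (0.0534). S-norcoclaurine synthase 1 (Pag368723), of alkaloid synthesis, differed by 1.97 (edgeR, adjusted p = 0.00968) and fell in both lines. The iron-sulfur assembly factor HCF101 (Pag233375) differed by -2.21 (edgeR, adjusted p = 0.0149) and rose in both. Feruloyl-CoA ortho-hydroxylase 1 (Pag133582) differed by 2.50 (edgeR, adjusted p = 0.0288), at -7.90 in AN-9 and -5.38 in L3. Cytosolic sulfotransferase 15 (Pag39926) differed by 2.64 (0.0283), the EMS1-like receptor kinase Pag74155 by -3.46 (0.0196), the nitrate transporter NRT1/PTR FAMILY 7.3 (Pag74845) by -2.76 (0.026), Pag81308 by -2.71 (0.0293) and the co-chaperone BAG6 (Pag270441) by -2.12 (0.0347). SBT1.6 (Pag165971) differed by 1.54 (0.0146) and the receptor kinase Pag125650 by 0.76 (0.0207).

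Of the 10415 shared genes tested, 194 differed (126 more positive and 68 more negative in L3), of which 158 changed less in L3, 28 changed more and 8 went opposite ways. Across 10272 shared genes, called or not, 30.8% had the larger change in L3, so smaller changes there prevailed among all of them. The number of genes that differed was 369 with the replicate number as a block and 613 with the DESeq2 Wald test. It fell to 118 without AN-9 unexposed library 2, 93 without AN-9 unexposed library 3, 121 without L3 unexposed library 1, 111 without L3 unexposed library 2 and 101 without L3 exposed library 1; Pag39926, Pag81308 and BAG6 each lost the call without any 1 of 8 libraries, Pag133582 without any 1 of 7, Pag74845 without any 1 of 3 and Pag74155 and Pag125650 each without any 1 of 2, with adjusted p up to 0.0851.

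**Figure D3:**
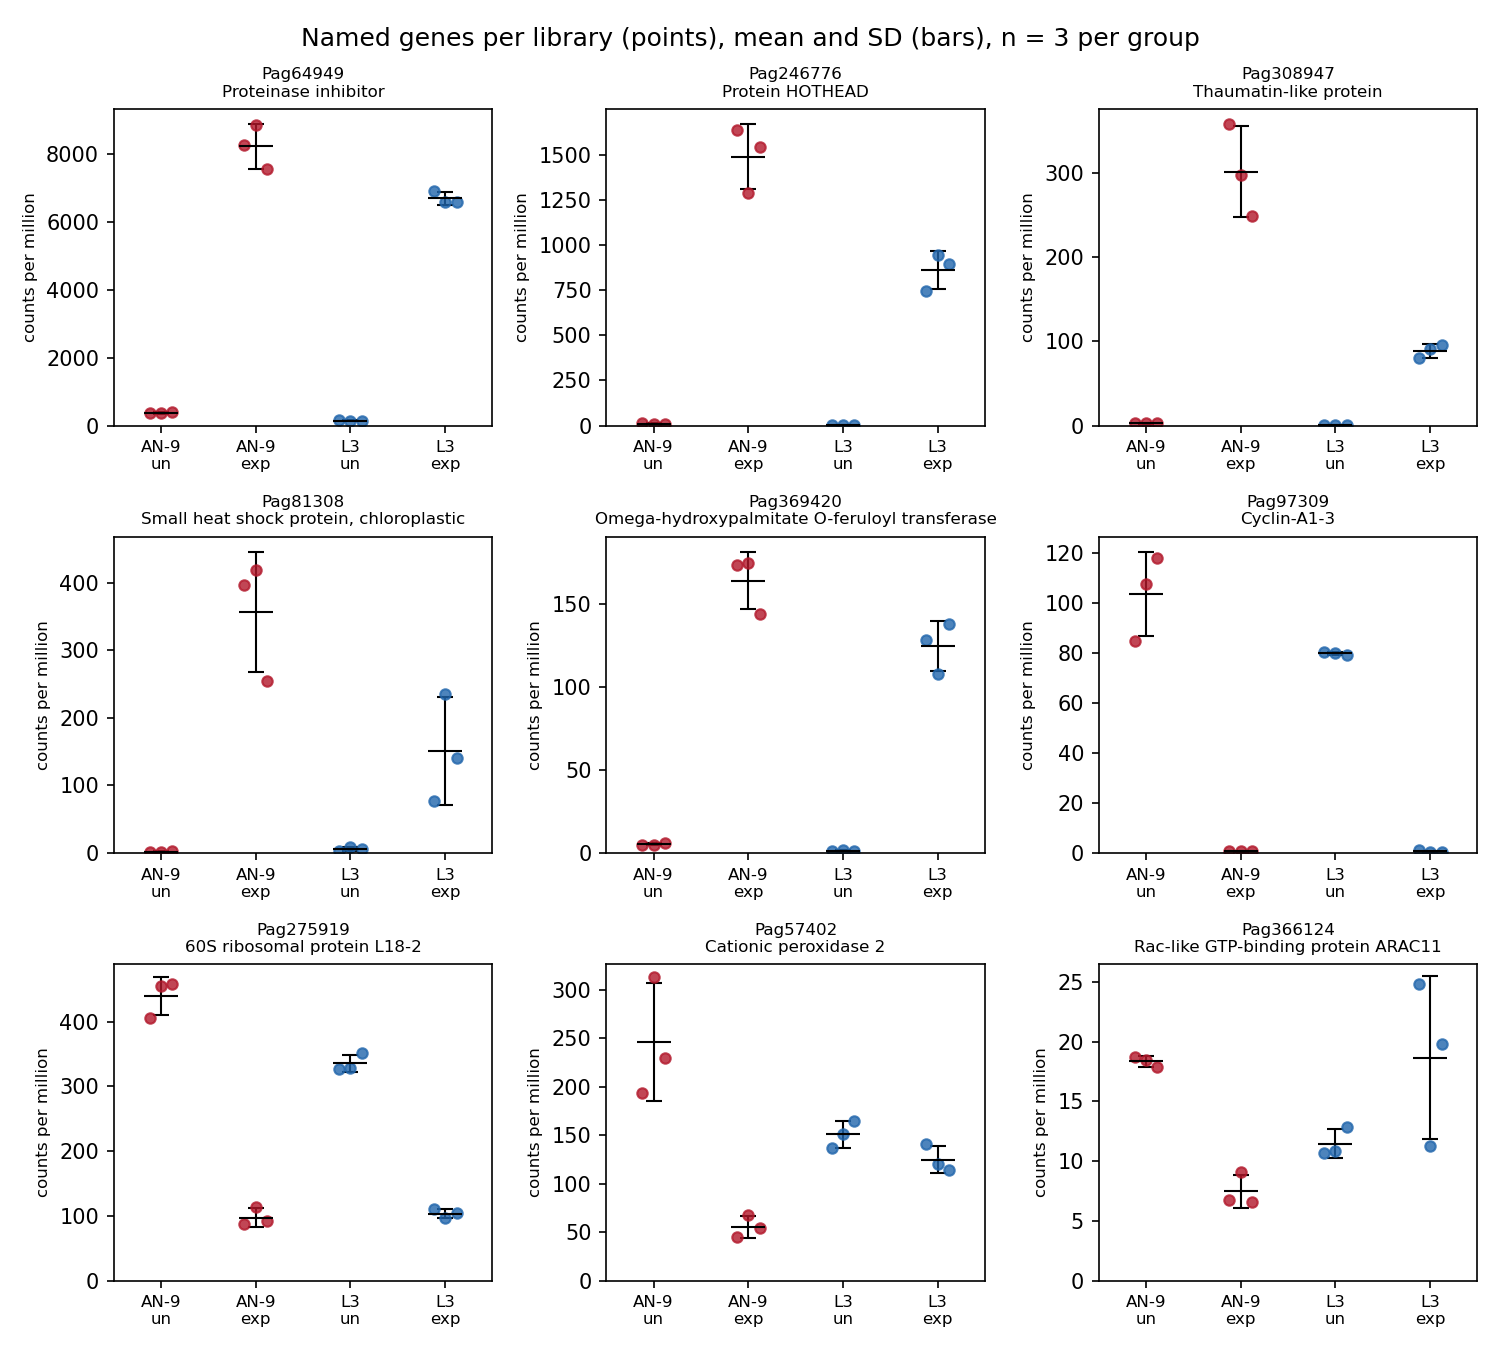
CPM of 9 named genes in each of the 12 libraries (points), with the mean and SD of each group (black bars, n = 3), in unexposed (un) and exposed (exp) AN-9 and L3. Cationic peroxidase 2 stood at a mean of 55.3 in exposed AN-9 and 125 in exposed L3, and the small heat shock protein Pag81308 at 357 and 152.

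The lines were also compared in filtrate. In filtrate, flavonoid genes were higher in L3 than in AN-9, with 16 of 25 higher and 3 lower and a median of 0.72 on the log2 scale (camera, adjusted p = 3e-04; adjusted p = 0.749 with an estimated correlation). Leucoanthocyanidin dioxygenase (Pag239272) stood at 42.0 ± 4.70 CPM in exposed L3 and 13.8 ± 2.26 in exposed AN-9 (SD, n = 3), a difference of 1.57 (edgeR, adjusted p = 6.55e-06). Phosphoenolpyruvate carboxylase (Pag143496), which fixes bicarbonate into oxaloacetate, stood at 57.6 ± 24.2 against 4.90 ± 1.07 (SD, n = 3), a difference of 3.52 (edgeR, adjusted p = 4.8e-05). The thaumatin-like Pag308947 was lower in L3, at 88.7 ± 8.13 against 301 ± 54.3 (SD, n = 3), a difference of -1.80 (edgeR, adjusted p = 3.22e-06).

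Phenylpropanoid genes (16 of 41 higher, 4 lower, median 0.27) and UDP-glycosyltransferases (8 of 29 higher, 3 lower, median 0.35) were also higher in exposed L3, each with adjusted p = 0.0497, and adjusted p = 0.749 with an estimated correlation. Ribosomal genes were lower, with a median of -0.10 (15 of 196 higher, 40 lower, adjusted p = 0.0241, and adjusted p = 0.827 with an estimated correlation). With the whole description the phenylpropanoid (0.0578), UDP-glycosyltransferase (0.0678) and ribosomal lists (0.0578) were not called, and none of these 3 was called without AN-9 exposed library 2 (0.0679, 0.0679 and 0.0701) or 3 (0.133 each). The phenylpropanoid list also lost its call without L3 unexposed library 3 (0.0528) and L3 exposed library 1 (0.0818) or 3 (0.125), the UDP-glycosyltransferase list without L3 exposed library 2 (0.055) or 3 (0.162) and the ribosomal list without L3 exposed library 2 (0.218). The first 2 lost it with a prior count of 0.5 as well (0.0514 each). The other 28 lists had adjusted p from 0.164 to 0.825, and of these the cell cycle list was called without L3 exposed library 1 (0.0207). The largest positive differences in filtrate were Pag247133, with a pollen Ole e I domain, at 3.68, Pag143496 at 3.52, cytochrome P450 71A9 (Pag312794) at 3.03, the mitochondrial chaperone GFA2 (Pag40572) at 2.92 and F-box protein 7 (Pag40732) at 2.91. Each of these was also higher in unexposed L3, by 2.82 to 3.92 (Pag247133 by 3.36, and by 4.14 without AN-9 unexposed library 3). The largest negative differences were the MADS-box gene AGL62 (Pag43486) at -2.94, Pag74155 at -2.67, PAG1 (Pag195767) at -2.62, the protease SBT4.3 (Pag45044) at -2.58 and a pectinesterase (Pag163808), which removes methyl groups from pectin, at -2.57.

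In the edgeR test 2859 of 10415 genes differed in filtrate, 1542 higher and 1317 lower in L3, which is 53.9% higher; with DESeq2 size factors 3112 differed, 1321 higher and 1791 lower, 42.4% higher. A scaling between lines rests on genes that changed in both, and the list tests between the lines were chosen after the data were examined.

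Without filtrate the comparison of lines gives the baseline. Ribosomal genes were lower in unexposed L3, 140 of 196 of them with a median of -0.36 (camera, adjusted p = 5e-20), as in L18-2 (Pag275919), at 336 ± 13.5 CPM against 440 ± 29.7 in AN-9 (SD, n = 3). Cell cycle genes were lower too, 31 of 99 against 5 higher (median -0.25, adjusted p = 0.00814). Heat shock genes were higher, 15 of 60 against 6 lower (median 0.28, adjusted p = 0.0239), and so were flavonoid genes (14 of 25, median 0.47, adjusted p = 0.00997) and phenylpropanoid genes (15 of 41, median 0.12, adjusted p = 0.0332). With an estimated correlation these lists had adjusted p = 0.72 (ribosomal, flavonoid and phenylpropanoid) and adjusted p = 0.795 (cell cycle and heat shock), and the other 27 lists had adjusted p from 0.116 to 0.983 with the preset one. With the whole description the heat shock (0.0758) and phenylpropanoid lists (0.0575) were not called and the NAC list was (0.0481). The heat shock list lost its call without AN-9 unexposed library 1 (0.0633) or L3 unexposed library 2 (0.131), and the phenylpropanoid list without L3 unexposed library 1 (0.0619) or L3 exposed library 1 (0.0598). NRT1/PTR FAMILY 7.3 (Pag74845) was higher in unexposed L3, at 6.54 ± 3.11 against 0.399 ± 0.245 CPM (SD, n = 3), a difference of 4.01 (edgeR, adjusted p = 5.76e-05), and DOWNY MILDEW RESISTANCE 6 (Pag140165) by 2.59 (edgeR, adjusted p = 0.00039). AGL62 (Pag43486) was lower by -4.56 (edgeR, adjusted p = 8.07e-05; without L3 unexposed library 1 it had 2 reads in L3 and 283 in AN-9, a ratio of 93.5, 95% exact binomial interval 25.7 to 776), and omega-hydroxypalmitate O-feruloyl transferase (Pag369420) by -1.92 (edgeR, adjusted p = 1.24e-05).

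In the edgeR test 3346 of 10415 genes differed without filtrate, 1579 higher and 1767 lower in L3, which is 47.2% higher; with DESeq2 size factors 3571 differed, 1354 higher and 2217 lower, 37.9% higher. The balance turned without L3 exposed library 1 (1794 higher and 1497 lower, 54.5% higher), without L3 unexposed library 3 (1391 and 1369, 50.4%) and with a log2 change of at least 1 (317 and 144, 68.8%).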

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

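The splits of the samples and the leave-out test of the heat shock list were planned before their outcomes were known. The results here were singled out because the filtrate response differed between L3 and AN-9 in the test of that difference.

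In the heat shock list 42 of 60 genes lay below 0, with a median difference of -0.27 between L3 and AN-9 (adjusted p = 3.44e-05; over its alternatives from 7.53e-09 to 0.951, the latter with an estimated correlation). A single library as the cause is argued against, since without each of the 12 libraries in turn the median stayed between -0.269 and -0.443 and the highest adjusted p was 0.00248. Chance was not excluded: 11 of 100 splits of the line labels within treatments, the real one included, gave a median difference as far from 0 (0.272 in the real split, 0.41 in the highest other). Of the 10 others 6 carried the lines' own difference unequally into the treatments, and among splits that carried it equally the largest was 0.355. Unexposed L3 lay above unexposed AN-9 by a median of 0.276 (15 of 60 genes higher and 6 lower, adjusted p = 0.0239; over its alternatives from 0.000889 to 0.795, and 0.0758 with the whole description). Exposed L3 against exposed AN-9 had a median of -0.15 (10 higher and 13 lower, adjusted p = 0.492). The difference in response is by construction the exposed difference between the lines minus the unexposed one. The list's mean log2 differences were -0.566 for the response, 0.44 unexposed and -0.126 exposed. In these means the larger part of the pattern lay in the higher unexposed level in L3. Why the levels differed was not tested and remains open.

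The ribosomal protein list differed by a median of 0.257 (adjusted p = 3.67e-18; over its alternatives at most 0.951, with an estimated correlation, and called in the others). Of the 32 lists, 2 were called for the difference, and 65 of 100 splits gave as many, with 8 in the highest other, so chance was not excluded for that number. For the 194 genes whose response differed, 9 of 100 splits gave as many, so chance was not excluded. The highest other had 4634 genes, with the lines swapped in 1 treatment, which points to the structure of the samples: all 8 other splits with as many genes carried the lines' difference unequally, while 40 splits carrying it equally gave at most 0 genes (edgeR). In those 40 splits each group mixed libraries of both lines, which puts the lines' difference into the spread within groups. Their 0 genes therefore give no support to the real grouping.

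Named genes that responded more positively in L3 were Pag39926 (2.64), Pag133582 (2.50), ARAC11 Pag366124 (1.98), Pag368723 (1.97), Pag57402 (1.86), Pag165971 (1.54), Pag369420 (1.49), Pag64949 (1.12) and Pag125650 (0.76) on the log2 scale. Those that responded more negatively were Pag74155 (-3.46), Pag74845 (-2.76), Pag81308 (-2.71), Pag233375 (-2.21), BAG6 Pag270441 (-2.12) and Pag195767 (-1.93).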

How the results depend on the processing

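The deposited size factors, the listed reads as library size, adjustment over the authors' number of genes, the whole description the higher minimum mean between the lines and all list settings between the lines were chosen after seeing the data. With a log2 change of at least 1 required, which removes smaller changes by construction, 5406 genes were called in AN-9 and 4649 in L3. The count of genes changed in the same direction in both lines was then 3887, with 77 for the difference of responses, 488 between exposed lines and 461 between unexposed lines. The difference of responses had 613 genes with the DESeq2 test and 369 with the replicate block (178 of the 194 among them); the cause was not tested. Leaving out 1 library gave 12021 to 12183 genes in AN-9, 11318 to 11529 in L3, 9908 to 10114 in both lines, 93 to 181 for the difference, 1944 to 2776 between exposed lines and 2348 to 3474 between unexposed lines. The lists called were 7 to 8 in AN-9, 8 to 11 in L3, 2 to 4 for the difference, 1 to 4 between exposed lines and 4 to 5 between unexposed lines. For the difference the counts were 118 and 93 genes without AN-9 unexposed library 2 or 3, 121 and 111 without L3 unexposed library 1 or 2, and 101 without L3 exposed library 1, and 4 lists without AN-9 unexposed library 1. Between exposed lines 1 list was called without AN-9 exposed library 2 or 3, 2 without L3 exposed library 2 or 3, and 2 with a prior count of 0.5. With an estimated correlation 0 lists were called in AN-9, 0 in L3, 0 for the difference, 0 between exposed lines and 0 between unexposed lines, and with the whole description 6, 4, 4, 1 and 4. In AN-9 the block called the salicylate and inhibitor lists and changed no other list call. In L3 the replicate numbers correlated at 0.0498, 0.121 and 0.194, and exposed 1 correlated best with unexposed 2 (0.0829), every other sample with its own number; with them as a block the heat shock (adjusted p = 0.0314), photosynthesis (0.0479) and hypoxia lists (0.0479) were called and the sugar list was not (0.0593). Of 404 values of called lists under alternatives 348 kept their call and 56 lost it. Of 1604 values of the 98 gene results picked by the naming rule 1568 kept it and 36 lost it. None of these changed direction. All 36 losses came with 1 library left out, in genes picked for the difference of responses. Genes picked within a line had been selected by the authors as changed, so their kept calls are not independent evidence. The higher minimum mean left 23 of 98 named values untested.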

Other observations

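The protein-domain families, the scaling test and the mixing test were chosen after the results they bear on were seen. The matched lists, the correlation of baseline and response and the splits of the samples were planned before their outcomes were known.

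Families of protein domains with at least 10 tested members gave 9 of 106 called in AN-9 and 8 of 100 in L3 by camera, and none with an estimated correlation (lowest adjusted p = 0.603 and 0.618). Pentatricopeptide repeat genes, which act on organelle RNA, fell in 61 of 66 cases in AN-9 (median -1.07, adjusted p = 3.15e-05) and in 49 of 50 in L3 (-0.92, adjusted p = 1.13e-05). All 20 genes with a cyclin C-terminal domain fell in each line (medians -2.67 and -2.54), as did 29 of 37 kinesin genes, of motors along microtubules, in AN-9 and 30 of 36 in L3. U-box genes, of ubiquitin ligases, rose in 30 of 37 cases in each line, ABC transporter domain genes in 20 of 24 and 20 of 25, and class 3 lipases in 11 of 12 and 12 of 13. Heat shock factor genes rose in 14 of 17 cases in AN-9 (adjusted p = 0.0375) and 12 of 17 in L3 (0.224), LSM genes fell in 12 of 12 (0.0177) and 11 of 13 (0.0814), and family 17 glycoside hydrolases in 15 of 18 (0.0303) and 15 of 19 (0.0528). GDSL lipases fell in 24 of 32 cases in L3 (0.0248) and 23 of 33 in AN-9 (0.0608), and MATE domain genes rose in 15 of 18 (0.0228) and 15 of 19 (0.0608). Over the 89 families tested for a difference in response between the lines the lowest adjusted p was 0.198 by camera.

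Ribosomal protein genes fell together in both lines. The highest median over 5 scalings and both lines was -0.762, in L3 with DESeq2 size factors, where the median of all genes was -0.193. A scaling moves all genes of a library alike, so it is argued against as the cause of the fall below the other genes. All 5 scalings are relative to the same libraries, so a change in total RNA could not be seen. Gene length and expression level are argued against, since 0 of 10000 lists matched on both had a median as low in either line (lowest -0.323 in AN-9 and -0.234 in L3). No biological explanation was tested.

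A hypothesis is that, among genes changed in both lines, unexposed L3 lay toward the exposed state. Correlations across genes, which are not independent replicates, that shared no library between baseline and response ranged from 0.0796 to 0.125, against 0.009 to 0.0143 in counts simulated without a relation. The simulated libraries were independent of each other, while AN-9 samples of the same number were taken as paired, so the simulated range may not hold here. The lowest observed correlation missed the bound of 0.1 set for a shift and all exceeded the 0.05 set against it, so a shift stays open. Exposed material mixed into the unexposed L3 libraries is argued against, since the 50 largest rises of L3 stood unexposed at a median of 3.58% of their exposed level (highest 5.28%), while the ribosomal list needs a share of at least 21.8%. The bound set, 10% of the share needed, was met with 39.8%, which takes unexposed AN-9 as the unmixed level, and not with 21.8%, and both references were tried. What made L3 a line of its own, selection included, stays untested.

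For the filtrate response 10 splits of 3 against 3 libraries are too few for a share under 0.05. In AN-9 the real split had 12464 genes and the highest other 0 (1 of 10 as large), and 7 lists against 10 (8 of 10 as large). In L3 the values were 11800 and 0 genes (1 of 10) and 8 and 10 lists (4 of 10). Between exposed lines they were 2859 and 1 genes (1 of 10), and between unexposed lines 3346 and 0 (1 of 10), also too few. Within each line other splits gave as many lists as the real one, and chance was not excluded for those numbers. Each of these splits held unequal numbers of exposed and unexposed libraries in its groups, so it carried part of the filtrate response. Their list counts are therefore no measure of chance and decide nothing. The genes of a line had been selected on the real grouping, so the 0 genes of its other splits decide nothing. In AN-9 the 3 other splits that part all 3 pairs gave 0 genes and up to 9 lists, and the splits that keep a pair together 0 genes and up to 10 lists. For genes changed alike in both lines 1 of 100 splits was as large (10244 against 0), but the genes had been selected on the real grouping, so this test decides nothing.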
